A study of Citrus x aurantiifolia with 4 samples.

How the data were processed

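RNA was extracted from leaves of wild-type plants and of transgenic plants of acid lime (Citrus x aurantiifolia, cultivar Pramalini) that overexpress a trypsin inhibitor of Putranjiva roxburghii, a tree of another family. Total RNA was purified on columns and treated with DNase, and libraries were made with a SMARTER mRNA-seq kit, per the labels' protocols. The series has 4 libraries, 2 per genotype, and the groups and replicate numbers were taken from the sample titles. Nothing in the labels says that the libraries of a genotype came from separate plants, so all p-values measure only the spread between these libraries, which may be technical.

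The submitters' processing notes name Bowtie2, RSEM and DESeq2, with no versions or settings given there. The feature names show that reads were counted against a de novo Trinity assembly, in which a read cluster (DN number) holds components (c), genes (g) and isoforms (i). How the assembly was made is not given in the sources used here, and neither is a genome build. Whether counting used the strand is not given either, so genes that share sequence, overlap or lie antisense may share reads. The files do not pair the assembled genes with names, and 0 of their IDs matched an entry of the gene table of the key lime assembly Mxlime_USDA_v1. The gene lists fixed before the data were examined (protease inhibitors, hormone, stress and photosynthesis pathways, and markers of other cell types and organisms) could therefore not be tested, and the introduced gene could not be looked up.

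In the form used here, 3 of the 4 tables end inside a row, and that last row was left out of each. How far these tables go on beyond that row is unknown, so their numbers of rows and shares of reads hold only for the part used here. The isoform table holds values with decimals, read here as RSEM expected counts, the tool being named per the file headers, and they were rounded to whole numbers for the count tests. The part used here has 184761 isoforms of 80304 genes. The gene value table holds the authors' normalized signal for 81380 genes. Its column sums differ between libraries and have a geometric mean of 1000000, as TPM (abundance corrected for transcript length and depth) multiplied by TMM factors would give, and the values are called TMM-scaled TPM here. Such values carry no read depth. The table that its name calls gene counts has 28097 whole rows. Within each library its values were the gene values times a constant (between 13.7533 and 13.7587 in wild type 1, over 10850 genes). They lay within 0.1 of the summed isoform counts for 5.68% of 27814 genes. It was therefore read as TPM signal scaled to the library's read total, not as reads per gene. The isoform table of TMM-scaled TPM signal that the authors deposited has 162803 whole rows in the form used here, and it was used only for alternatives.

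The constants give the read total of each library, 13510172 and 17357248 for wild type 1 and 2 and 17694542 and 16062324 for transgenic 1 and 2. The isoform table holds 97.57% to 97.93% of these reads. A count of 0 allows up to 3 reads in a library, and this floor covers counting error only.

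The gene-level test had been planned as an edgeR count test. Because the gene tables hold no reads, it was replaced, once the unit was known, by limma-trend (limma 3.58.1, R 4.3.3) on log2(value + 1), over genes with a value of at least 1 in at least 2 libraries, transgenic against wild type. Fold changes are on that scale, which understates the change of genes with low values. Isoforms were tested with edgeR 4.0.16 by its quasi-likelihood test with TMM factors and filterByExpr at its defaults (minimum count 10). Isoform usage within genes was tested with edgeR's diffSpliceDGE, with Simes p-values per gene. All p-values are two-sided and were adjusted by Benjamini-Hochberg, and adjusted p under 0.05 was called. Genes found in 1 genotype only had at least 10 reads (summed isoform counts) in both of its libraries and 0 in both others, in the isoform table and in the gene value table. The named genes were set by a rule written before the data were examined. In each direction it takes the gene with the smallest p among called genes read in every library, and the called gene of 1 genotype only that has the most reads.

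The tests were checked on simulated data with the means and spread of the real libraries. With 30% of genes changed, the limma test of 34378 genes recovered 48.9% of genes changed 2-fold, 77.9% of those changed 4-fold and 93.9% of those changed 16-fold, with 337 false calls among 7923. With 30.1% changed, the edgeR test of 66795 isoforms recovered 9.79%, 58% and 97.8%, with 435 false calls among 11504. With 29.7% changed, the usage test of 15601 genes recovered 1.09%, 7.46% and 53.5% of genes whose isoforms moved apart by these folds, with 76 false calls among 1027. With few changed features the limma test made 0 calls (198 genes changed), 13 of 48 edgeR calls were false (178 isoforms changed) and 22 of 32 usage calls were false (181 genes changed). These shares of changed features were set for the simulation and are not estimates.

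Alternatives were DESeq2 1.42.0, other scalings, filters and pseudocounts, a fold change limit, the replicate number as a block, gene reads summed from isoforms, other minimum counts, and each library left out in turn, when the lone library of a genotype was assumed to vary like the other genotype's pair. The test as first planned, edgeR on the part table of scaled values, was run as an alternative chosen after the files were seen. Dixon's outlier test needs groups of 4 and was not run.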

Results

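Leaf RNA of wild-type acid lime (WT, 2 libraries) was compared with leaf RNA of plants overexpressing a trypsin inhibitor of Putranjiva roxburghii (TG, 2 libraries). Trypsin inhibitors are proteins that block serine proteases, and plants use them against herbivores and pathogens. The series title places the comparison in a study of tolerance to several stresses. The read totals implied by the gene tables were 13510172 and 17357248 in the WT libraries and 17694542 and 16062324 in the TG libraries, over an assembly of 81380 genes. Between 33393 and 35046 of these genes had a TMM-scaled TPM of at least 1. The 10 most abundant genes made up 9.5% ± 0.535 of the total signal in WT and 11.8% ± 1.11 in TG (mean ± SD, n = 2). An exact permutation test of 2 libraries against 2 cannot go below p = 0.333, the value obtained for this share (two-sided), so no single measure can be called with it.

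Libraries of the same genotype resembled each other far more than libraries of different genotype. Across the 34378 genes tested, log2 values correlated with Pearson's r = 0.945 between the WT libraries and 0.917 between the TG libraries, against 0.694 to 0.742 between genotypes. These correlations are across genes, which are not independent replicates. The median absolute log2 difference of a gene was 0.27 between the WT libraries and 0.36 between the TG libraries. Between genotypes it was 0.70 to 0.80. The chi-square per degree of freedom over summed reads per gene, whose reference is counting error only, was 29.7 between the WT libraries and 72.1 between the TG libraries.

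**Figure D1:**
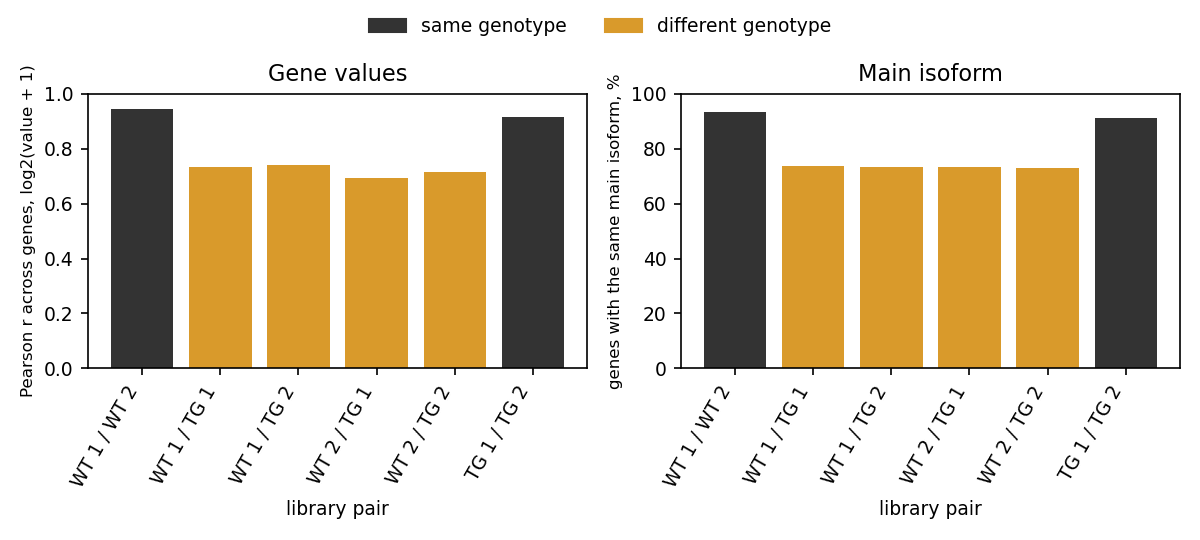
Similarity of the 6 pairs of libraries, with pairs of the same genotype in dark grey and pairs of different genotype in orange. The left bars show Pearson's r across 34378 genes and lie at 0.694 to 0.742 between genotypes, and the right bars show the percentage of 14089 genes with the same main isoform, at 73% to 73.6% between genotypes.

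The genotypes differed in 9018 of 34378 genes (26.2%) by limma at an adjusted p under 0.05. Of these, 4272 genes were higher in TG and 4746 were lower. Most of the called differences were large, with 4011 higher and 4530 lower genes changed at least 2-fold. At least 32-fold changes were found for 109 higher and 126 lower genes. Over all genes tested the median log2 change was 0.02, with quartiles at -0.67 and 0.60. Without the filter on low values 1845 of 75968 genes were called, and with a library left out the count was 2482 without WT 1, 2340 without WT 2, 2393 without TG 1 and 2496 without TG 2. The balance of directions among the calls moved as well, towards lower in TG when a WT library was left out and towards higher when a TG library was left out. In such a fit the spread comes only from the genotype that keeps both libraries. The median log2 change stayed near 0.02, at -0.0107 without WT 1, -0.00687 without WT 2, -0.015 without TG 1 and 0.00397 without TG 2.

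Abundant and rare genes were both affected. Among genes with a mean value under 10, 2748 were higher and 3224 lower, or 31.5% of 18973. In the range of 10 to 100 the share was 19.7% of 13978 genes, and in the range of 100 to 1000 it was 20.8% of 1361 genes. Of the 66 genes with a mean value of 1000 or more, 5 were higher and 10 lower. Genes assembled as 1 isoform were called in 35.8% of 10631 cases. Genes with 2 to 4 isoforms were called in 23.7% of 12966 cases and those with 5 or more in 19.4% of 10578. Genes that were alone in their assembly component and genes that shared it with others were called in 27.5% and 25.4% of cases.

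**Figure D2:**
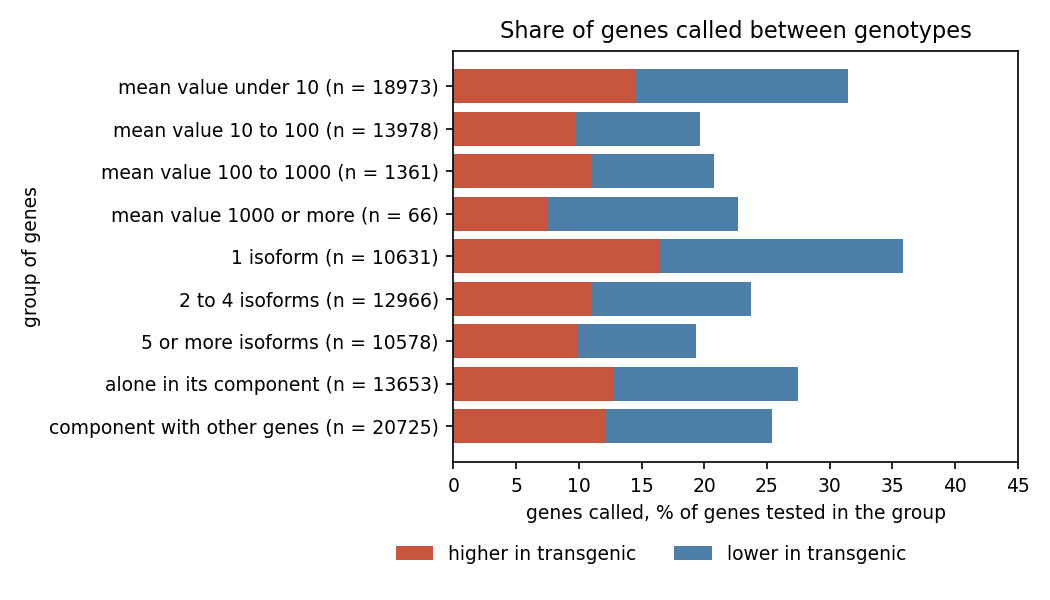
Percentage of tested genes called by limma (adjusted p under 0.05) in groups set by the mean TMM-scaled TPM over the 4 libraries, the number of isoforms and the assembly component. Red is the part higher in transgenic leaves and blue the part lower, and the share is highest, at 35.8%, for genes of 1 isoform.

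A pair of genes from a single read cluster took the first and second place by reads in both TG libraries and had few reads in WT. TRINITY_DN21553_c1_g2 had a TMM-scaled TPM of 4742 ± 556 in TG and 0.23 ± 0.04 in WT (mean ± SD, n = 2). Its log2 change was 11.91 (SE 0.18, limma adjusted p = 0.0057). It was covered by 122215 and 135188 reads in the TG libraries and by 6 and 5 reads in the WT libraries. Its partner, picked out after its values were seen, held 310598 reads in TG 1 and 178185 in TG 2, or 1.76% and 1.11% of all reads, against 7 and 11 reads in WT 1 and WT 2. Its log2 change was 12.85 (SE 0.34, limma adjusted p = 0.0068). By TMM-scaled TPM neither gene of the pair came first. The most abundant gene held 4.135% of the total signal in TG 1 and 3.611% in TG 2. The files do not say what either gene of the pair encodes.

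TRINITY_DN16680_c3_g4 was read in TG only. It had 1878 and 4484 reads in the TG libraries and none in the WT libraries, with a TMM-scaled TPM of 942 ± 342 in TG (n = 2). In CPM, reads scaled to the read total, it was at least 976-fold higher in TG, taking the floor of 3 reads in each WT library, and at least 538-fold without TG 2. The limma log2 change was 9.83 (SE 0.31, adjusted p = 0.0068). Of the 10 genes tested in its read cluster, 7 were called lower in TG. The one among them with the largest limma log2 change, looked up after the values were seen, had a TMM-scaled TPM of 561 and 1295 in the WT libraries and of 0 and 0.443 in the TG libraries (limma log2 change -9.47, SE 0.48, adjusted p = 0.0075). The other named genes had fewer calls against their own direction in their read clusters. These were 0 of 4 genes tested for TRINITY_DN21553_c1_g2, 0 of 2 for TRINITY_DN21191_c1_g1 and 1 of 3 for TRINITY_DN13809_c1_g2.

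TRINITY_DN21191_c1_g1 was read in WT only. It had 1876 and 2159 reads in the WT libraries and none in the TG libraries, with a TMM-scaled TPM of 54.6 ± 6.0 in WT (n = 2). It was at least 739-fold lower in TG on the same floor, and its limma log2 change was -5.79 (SE 0.23, adjusted p = 0.0068). All 5 of its isoforms with counts in the table were read in both WT libraries and in neither TG library.

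TRINITY_DN13809_c1_g2 had the smallest p among the genes that were lower in TG and read in every library. Its TMM-scaled TPM was 446 ± 30 in WT and 4.3035 ± 0.0049 in TG (n = 2), with a log2 change of -6.40 (SE 0.16, limma adjusted p = 0.0068). Its reads fell much less, from 145 and 171 in WT to 72 and 76 in TG. One of its isoforms was read in WT only, with 77 and 106 reads worth 416 and 468 units of TPM. The other isoform kept 65 to 76 reads, worth 3.40 to 4.56 units, in all 4 libraries. On summed reads the log2 change was -1.07 (edgeR adjusted p = 0.036) or -1.09 (DESeq2 adjusted p = 0.0651), and over all its alternatives in limma, edgeR and DESeq2 the adjusted p ranged from 0.00173 to 0.0651.

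**Figure D3:**
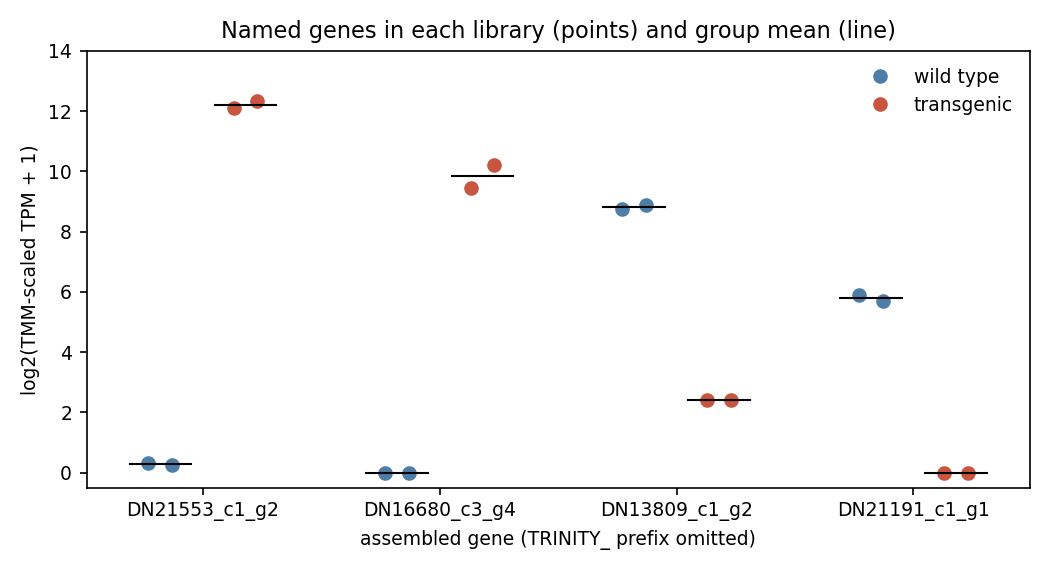
TMM-scaled TPM of the 4 named genes on a log2(value + 1) axis, with a point for each library (blue wild type, red transgenic) and a line for the group mean. The genotypes do not overlap for any of the 4 genes, and TRINITY_DN16680_c3_g4 and TRINITY_DN21191_c1_g1 sit at 0 in the genotype that lacks their reads.

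Such a gap between values and reads was found in a minority of the called genes that could be compared. Of the 9018 called genes, 6707 had at least 20 reads over the 4 libraries, and the rest were not compared. In 98.6% of the 6707 the summed reads had the same direction as the values, as also for TRINITY_DN13809_c1_g2. The 2 log2 folds lay more than 2 apart in 555 genes (8.27%). The edgeR test on reads summed per gene called 9100 of 29263 genes, 4269 higher and 4831 lower. It shared 5580 calls in the same direction with the limma test and 4 in the opposite direction.

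Reads in 1 genotype only were found for 624 genes in WT and 650 genes in TG. The libraries grouped in either of the other ways, each group holding a library of each genotype, gave 0 such genes in all 4 groups. Most of these genes were rarely read, with a median of 67.7 reads over the WT libraries and 75 over the TG libraries. Together they held 0.274% and 0.379% of the reads in WT 1 and WT 2, and 0.348% and 0.412% in TG 1 and TG 2. Mean values of 100 or more were reached by 8 of the WT genes and 9 of the TG genes. A single isoform made up 52.9% of the WT genes and 50.8% of the TG genes, against 22.2% of the 29282 genes with at least 10 reads in at least 2 libraries. These 29282 genes were not matched to them in read level, so the shares do not set genes of 1 genotype apart. The limma test covered 528 of the WT genes and called 508, and it covered 533 of the TG genes and called 517. These genes were picked for values of 0 in 1 genotype in the same libraries, so the calls add no separate support. With the condition set on a lone library, the WT number rose to 980 without WT 1 and to 942 without TG 2, and the TG number rose to 1015 without TG 1.

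Isoforms were called in large number in both directions. The edgeR test called 32670 of 71940 isoforms (45.4%), 16525 higher and 16145 lower in TG, and on reads summed per gene it called 31.1% of genes. The called isoforms belonged to 17377 of the 28317 genes with a tested isoform, and their median absolute log2 change was 4.34. The common biological coefficient of variation between replicates was 39.4%. Without WT 1 the count was 17528, and without WT 2 it was 15749.

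Where a gene was called, its called isoforms mostly pointed the same way. Of the 2861 genes called higher that had a tested isoform, 2709 had an isoform called higher and 376 one called lower. Of the 3338 genes called lower, 3165 had an isoform called lower and 321 one called higher. Several isoforms were tested in only 1636 of the genes called higher and 1680 of those called lower. Isoforms called in both directions were found in 368 of these 1636 genes and in 313 of these 1680. The remaining called genes could not hold both directions, so they raise the agreement. Many genes that were not called also held called isoforms. Among 20558 such genes, 7613 had an isoform called higher, 7203 had one called lower and 3973 (19.3%) had both. Several isoforms were tested in 13241 of these 20558 genes.

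The isoforms that a gene used also differed between genotypes. The usage test called 9293 of 16609 genes with at least 2 tested isoforms (56%, edgeR diffSpliceDGE, Simes, adjusted p under 0.05), and 7619 of these genes were not called by the gene-level test. Without WT 2 the count was 5996. The main isoform, the one with the most reads of its gene, was compared in 14089 genes with several isoforms and at least 50 reads in every library. It was the same in 93.3% of them between the WT libraries and in 91.3% between the TG libraries, but in 73% to 73.6% between genotypes. In 2487 genes (17.7%) both libraries of a genotype agreed on the main isoform and the genotypes differed, against 33 and 35 genes when the libraries were grouped in the other ways.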

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

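The limma test at gene level, listed beforehand as an alternative, became the reported one after the files were seen, and the tests added then were the edgeR test on the part table, the library sizes from the gene tables, the restricted genes and the fold bounds of the named ones without each library, and the removal of WT-specific genes of unequal ratio. Of 131 alternative values, 109 kept their side of the threshold, stayed within 1.5 times the reported count or, for a fold bound, moved by less than the spread between replicates. None reversed direction. Most of the 131 belong to the named genes, which were picked for a small p or many reads. Some of the 109 could not come out otherwise. These include fold bounds without a library of the genotype that was read, and the fold change limit for the named genes. The TG genes after removal of WT-specific genes are another case. The 21 that moved were all counts, among them each gene count with a library left out. A like count can hold other genes. DESeq2 on summed reads called 8464 genes, and 5267 of them were among the 9018 in the same direction. The 9018 gene calls became 1845 without the filter on low values, all of them among the 9018. They became 4841 with edgeR on the part table, which covers fewer genes and also changes the test and the filter. Isoform calls became 17779 with limma on normalized values without a filter. The cause was not tested for the filters or for the part table. Genes of 1 genotype numbered 1123 (WT) and 1050 (TG) at a minimum of 5 reads, 183 and 207 at 50 reads, and 0 and 0 when the libraries were paired in either of the other ways. Leaving out a library gave 2340 to 2496 gene calls, 15749 to 26515 isoform calls, 5996 to 8121 usage calls, 698 to 980 WT genes and 780 to 1015 TG genes. Without a WT library most gene calls were lower in TG, and without a TG library most were higher. In such a fit the spread comes only from the genotype that keeps both libraries. The median log2 change of the genes tested stayed at -0.015 to 0.00397, so this balance of calls does not measure the direction of change. With all 4 libraries 47.4% of gene calls were higher in TG. Scaling moved this share to between 43.4% and 47.9%. Without a composition factor the median log2 change of isoforms moved from 0.03 to -0.14. The replicate number as a block gave 9626 gene, 22489 isoform and 8464 usage calls. The labels do not say what the numbers share, and the deviations of same-numbered libraries correlated at r = 0.105 across genes, so the block was not used as the design. TRINITY_DN13809_c1_g2 was not called by DESeq2 on summed reads (log2 change -1.09, adjusted p = 0.0651), while its adjusted p was 0.00173 to 0.036 in its other limma and edgeR alternatives. The set test of gene lists could not be run because the files give no gene names. A count of 0 allows up to 3 reads in a library, and no count of restricted genes at matched depth was run.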

Other observations

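Tests chosen only after their result was seen are those of components, of the correlation over read clusters, of the scaling between WT libraries, of the genes at like level in both genotypes, and of the trace reads. The tests of isoforms called in both directions, of the called share over read clusters and of partners in a read cluster were set before. The other pairings of the libraries were planned, and only the bound their counts were held to was set afterwards. The share of WT-specific genes with a high ratio was also set afterwards as a test.

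Among 311 WT-specific genes (at least 50-fold higher in WT, at least 200 WT reads and at least 20 in each WT library), 109 had a WT 2 to WT 1 log2 ratio above 1. These 109 genes held 0.768% of the reads of WT 1 and 2.06% of those of WT 2. They had 461750 WT reads and 1750 TG reads. A log2 ratio below -1 was found for 7 of the 311. On the TG side the ratios went both ways, with a TG 2 to TG 1 log2 ratio below -1 for 34 (12.3%) and above 1 for 20 (7.25%) of 276 TG-specific genes, against 4.23% and 3.14% of genes at like level. The 34 genes held 1.65% of the reads of TG 1 and 0.0967% of those of TG 2.

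The first pattern is the number of genotype differences. Uneven sampling between libraries is argued against for the genes read in 1 genotype only. Other pairings of the libraries gave 0 such genes, against 624 and 650. These pairings do not cover the other called genes and isoforms. Anything else that both libraries of a genotype share, such as a plant or a preparation, cannot be told apart from genotype here. Sequence variants of a locus, assembled apart in plants that differ in their alleles, are a candidate explanation. After the genes of each read cluster were summed, 15.3% of read clusters were still called. This is below each of 20 random groupings of the same sizes (18.9% to 20.8%), a drop in the direction that variants predict. The calls that remain cannot exclude variants as the whole cause, because variants assembled into different read clusters are not summed. Summed TPM also need not cancel between variants of unequal length. The counts of genes with isoforms called in both directions (4665, random reassignments of the calls from 5055) and of components with genes called in both directions (432, random 419 to 506) leave open whether variants replace each other, which cannot be told apart here, because isoforms that move with their gene lower such counts, so the reading of a low count set before was wrong. Variants stay open as a part or the whole of the cause, like the effect of the introduced gene. As a part of the cause they would raise the mean correlation between genotypes. It rose from 0.721 over genes to 0.84 over read clusters, above the 0.776 reached by random groupings. The mean correlation within genotypes rose as well, from 0.931 to 0.946. Summing genes of a read cluster that share reads could also raise the correlation, so the rise does not single out variants.

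The second pattern is the share of WT-specific genes with a WT 2 to WT 1 log2 ratio above 1, 35% against 1% of genes at like level in both genotypes. A single scaling error between the WT libraries is argued against, since it would move all genes alike. The 12100 genes at like level had a median log2 ratio of -0.0103, against 0.539 for the 311 WT-specific genes. The first value alone decides nothing, because TMM factors set the bulk of shared genes near 0. A citrus gene program that takes in such genes as often as WT-specific ones is argued against by the 1%. The shares were 1.48% against 30.7% when the levels of both sets were judged on WT 1 and TG alone. This keeps a rise in WT 2 out of the level filter, but the minimum reads still counted both WT libraries. A rise in WT 2 could thus still help a gene pass. A program that takes in only a small part of the genes at like level is not excluded. Of these genes, 121 had a log2 ratio above 1 and 166 one below -1. RNA of another source, such as another organism or tissue, may account for it, as a hypothesis. A partner expressed in TG was found in the read cluster of 57.8% of the 109 genes and of 73.3% of the other 202 WT-specific genes (Fisher's exact test, two-sided, p = 0.00737, genes not being independent). This is the direction that RNA of another organism would give, while RNA of another tissue need not give it. Most of the 109 still had a partner. The 2 sets also differed in read level, with a median of 1320 WT reads for the 109 and 420 for the 202. A citrus gene program of WT-specific genes alone would give the same 35% and cannot be told apart from RNA of another source, because no gene has a name.

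The third pattern is the pair of genes that lead the TG libraries by reads. RNA from the introduced construct is a candidate source, as a hypothesis, and WT reads came to at most 0.00427% of the TG reads. That value does not bear on the source, because the genes were picked for near absence from WT, and the WT-specific genes picked in the same way had 0.0259% and 0.0154% of their WT reads in TG. The construct cannot be told apart from RNA of a virus or another organism in the TG plants, because neither gene has a name or sequence in the tables used here.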
